A study of Mus musculus with 15 samples.

How the data were processed

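RNA was measured in NIH3T3 cells, an established line of mouse embryonic fibroblasts that stops dividing in low serum and re-enters the cell cycle when growth factors return. Per the labels' protocols, 1 µg of total RNA per sample went into library construction, messenger RNA was captured on beads carrying oligo-dT, the RNA was fragmented, and cDNA was primed with random hexamers. Whether the library kit marked strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. The labels place the 15 libraries in 5 groups of 3, numbered 1 to 3 within each group. They do not say that the libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be partly technical. Doses, times and the length of starvation are not given in the sources used here.

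Each deposited file holds whole-number read counts for 142446 mouse transcripts, not normalized, per the file contents. The submitters' processing notes name HISAT2 2.2.1, HTSeq 0.9.1 and R 4.1.0, and they name the genome build hg38. That is a human assembly, and the identifiers in the files are those of mouse transcripts, so it is unlikely to be the build that was aligned to, and the authors' mouse build and annotation release are not given in the sources used here. The identifiers were matched to the GENCODE M21 annotation of the mouse assembly GRCm38 after removal of the version number. Of the 142446 identifiers, 141536 matched, 141117 of them with the same version, and the 910 unmatched transcripts carried 0.0309% of all counts and were left out. Counts were summed per gene identifier, which gave 55266 genes, and genes that share a symbol were kept apart. No read was found in any library for 89291 transcripts. All coordinates are 1-based and on GRCm38, from that annotation.

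The way the reads were counted limits which genes could be seen. By default HTSeq drops a read that falls on more than 1 feature, and in these files genes whose transcripts all overlap had few reads. None of the 314 protein-coding genes without a base that belongs to a single transcript had a mean count of 10 or more, against 7273 of the 20037 with over 200 such bases. Counts per library ran from 0 to 2 for *Actb*, from 14 to 41 for *Gapdh*, from 0 to 61 for *Egr1* and from 24 to 27441 for *Fos*. A gene's sum therefore reflects reads specific to individual transcripts, and a shift between isoforms can change it. Reads of histone genes and other near-identical families may also be split between copies. Levels of different genes cannot be compared with each other for the same reason.

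The total count per library ran from 3466202 to 6777780. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with robust estimation of the spread, on the counts as deposited after the sum per gene. Genes were filtered with filterByExpr over the 5 groups, which left 10603, and libraries were scaled by the trimmed mean of M-values (TMM). All 15 libraries entered a common fit with a mean per group, which leaves 10 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the 10603 genes. A gene was called changed at an adjusted p under 0.05. Fold changes are given on the log2 scale with an approximate standard error (SE), the absolute log2 change divided by the square root of the F statistic. Being back-calculated from the test, it may understate the error where a group has few reads. Levels are given as TMM-normalized CPM, a gene's reads relative to the scaled total of its library, with the standard deviation (SD) over the 3 libraries of a group. Where a group had no read of a gene, the fold is a lower bound against a floor of 3 counts over the 3 libraries; with 1 to 3 reads it is a ratio of counts with its exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

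The comparisons were PDGF against no PDGF, rapamycin with PDGF against PDGF, cycloheximide with PDGF against PDGF, and TerminaTOR against mCherry with both cycloheximide and PDGF. In addition, rapamycin with PDGF and cycloheximide with PDGF were each compared with no PDGF, and the rapamycin and TerminaTOR effects were compared by a test of their difference and by Fisher's exact test of shared calls. Comparisons that share libraries share chance values, so 20 simulations of unchanged groups give the value expected from that alone. The 5 groups, the comparisons, the tests, the 36 gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. By that rule the text names, per main comparison, the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the replicates of the groups, leaving out predicted genes and pseudogenes by the form of their symbol. It adds up to 3 called members per list with the smallest adjusted p, *Fos*, *Egr1* and *Myc* throughout, and the 10 genes changed in the same direction and the 5 changed in opposite directions by rapamycin and TerminaTOR with the smallest larger adjusted p; list members may be left out for readability, and some named genes are not reported here.

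The lists cover immediate early genes; MAPK feedback inhibitors; SRF and MRTF cytoskeletal targets; cholesterol synthesis; fatty acid synthesis; glycolysis and HIF1 targets; the pentose phosphate pathway; ATF4 and the amino acid response; ribosome biogenesis factors; cytosolic ribosomal proteins; translation factors; RNA polymerase III; TFEB and lysosome genes; G1 and S phase genes; mitosis genes; FOXO and quiescence genes; and cytokine and NF-kB target genes. They also cover interferon response genes, extracellular matrix, oxidative phosphorylation, ER chaperones, NRF2 targets, p53 targets, heat shock genes, snoRNA host genes, nucleotide synthesis, mTORC1 components, PDGF receptors and ligands, and histone H2A genes. Mitochondrially encoded genes and nuclear retained RNAs stand for RNA quality, and markers of macrophages, epithelium, endothelium, adipocytes and muscle for other cell types. Lists with at least 2 tested members, 33 of the 36, were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Counts of called members are given as adjusted over all genes and as adjusted over the list alone.

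The alternatives were median-of-ratios and library-size scaling, no filter beyond a total count above 0, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit on the compared groups only, the replicate number as a block, transcripts as deposited, each replicate left out in turn, a 2-fold minimum, an adjusted p under 0.01, and camera with an estimated correlation and fry for the lists. Replicates were checked for duplicates by a chi-square test of their counts. The statistic per degree of freedom ran from 2.39 to 6.85, so no pair was within sampling noise.

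The test was tried on simulated data made from the means and library sizes of the TerminaTOR comparison, with 50 genes changed at each of 4 sizes, and the filter left 10277 genes to test. It recovered 54% of the genes changed 1.5-fold, 58% of those changed 2-fold, 74% of those changed 4-fold and 86% of those changed 8-fold. It also called 8 unchanged genes. A simulated list with a shared rise was called by camera, as were 2 of the 32 other lists, both of which held genes simulated as changed. Genes were simulated independently, and the rise was larger than the medians of the lists called in TerminaTOR cells. The trial therefore does not test camera on lists whose members are correlated, such as mitosis genes (estimated correlation 0.23). Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.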

Results

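The series addresses transcription under the control of mTORC1, a kinase complex that couples growth factors and nutrients to cell growth, and of the share of it that acts in the nucleus. NIH3T3 mouse fibroblasts carried a doxycycline-inducible fusion of histone H2A to mCherry, the control, or to TerminaTOR, a genetically encoded mTORC1 inhibitor that the histone holds in the nucleus. The cells were starved and then given PDGF, a growth factor that drives fibroblasts to divide. There were 5 groups of 3 libraries: control cells without PDGF, with PDGF, with rapamycin and PDGF, and with cycloheximide and PDGF, and TerminaTOR cells with cycloheximide and PDGF. Rapamycin inhibits mTORC1 throughout the cell, and cycloheximide blocks translation, so that RNA changes that arise under it do not depend on newly made protein. TerminaTOR has to be translated as well, so indirect effects of its expression before the block are not excluded. The times of doxycycline and cycloheximide are not given in the sources used here, and the level of TerminaTOR was not measured.

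The total count per library was 4521177, 3892398 and 4406994 without PDGF, 3579179, 3875359 and 4721169 with PDGF, and 3799195, 3494761 and 4652663 with rapamycin and PDGF. It was 5302795, 4343791 and 5579478 for control cells with cycloheximide and PDGF, and 6777780, 5474897 and 3466202 for TerminaTOR cells. In a principal component analysis of log2 CPM, the groups without cycloheximide lay on the negative side of the first component, which held 42.8% of the variance, and the groups with cycloheximide on the positive side. The second component held 26.3% and ran from the libraries without PDGF to those with rapamycin and PDGF.

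**Figure D1:**
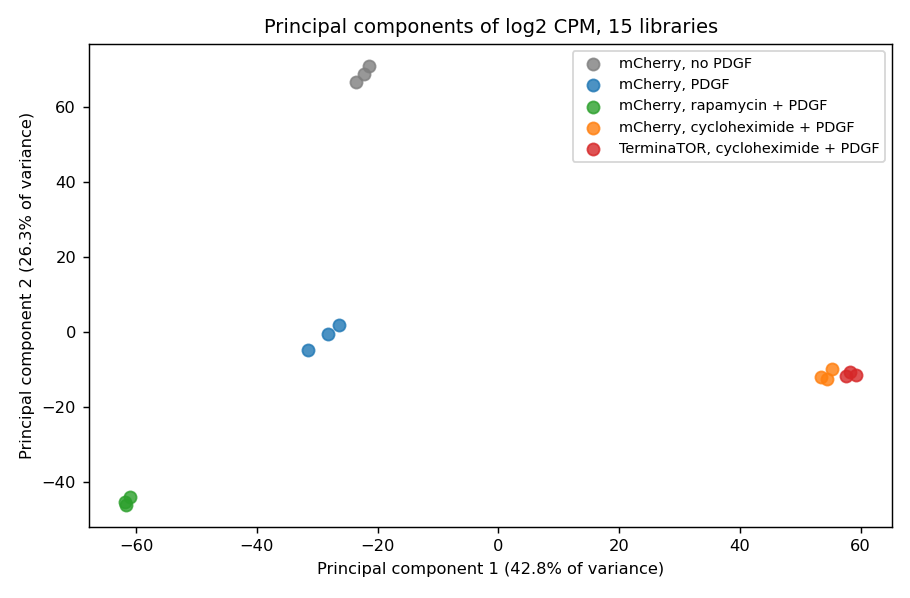
Each point is a library, coloured by group, placed by its scores on the first and second principal components of log2 CPM over 10603 genes, with the share of variance on each axis (42.8% and 26.3%). The 3 libraries of a group lie together, and the control and TerminaTOR groups with cycloheximide lie next to each other.

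The PDGF comparison asked what the growth factor does in control cells. PDGF raised immediate early genes, which respond to growth factors before new protein is made. *Fos*, an AP-1 subunit gene (ENSMUSG00000021250.13, GRCm38 chromosome 12, 85473890 to 85477273), rose by a log2 change of 4.59 ± 0.15 SE, to 139 ± 6.24 from 5.73 ± 1.36 CPM (SD, n = 3). *Phlda1*, on chromosome 10 (111506286 to 111508645), rose 24.4-fold (149 ± 11.5 against 6.07 ± 0.355 CPM) and *Btg2*, an antiproliferative gene, 39.1-fold. *Ptgs2* (ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227), which encodes the prostaglandin synthase COX-2, rose 12.6-fold from 931 ± 77.3 to 11717 ± 320 CPM, and *Thbs1*, a matrix glycoprotein, 6.16-fold from 1505 ± 78.8 to 9276 ± 546 CPM. *Mn1*, a transcriptional coregulator, fell by 3.33 on the log2 scale, from 495 ± 34.1 to 49.5 ± 7.95 CPM, and *Smad6*, an inhibitor of BMP signalling, was 11.4-fold lower. These changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.03e-15 for *Fos*, 2.87e-55 for *Ptgs2*, 3.24e-44 for *Mn1*).

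Of 32 immediate early genes tested, 30 rose and none fell (31 and 0 adjusted over the list alone), with a median log2 change of 2.59, or 2.35 with the member at 0 reads set to its bound (camera adjusted p = 1.84e-76). *Klf4*, a transcription factor, rose 5.83-fold, *Myc* 3.73-fold (78 against 26 reads per group) and *Egr1* from 6 to 18 reads, a call (edgeR adjusted p = 0.0346) that was lost without replicate 2 or 3 of the group without PDGF, without replicate 1 or 2 of the PDGF group (adjusted p up to 0.170), without a filter and under library-size scaling. MAPK feedback inhibitors, which damp the pathway that PDGF activates, rose in 12 of 14 and fell in 1 (12 and 1 over the list alone, camera adjusted p = 4.97e-32). Among them were the phosphatase gene *Dusp5* (12.1-fold), *Spry2* (11.5-fold) and *Spry4* (23.3-fold). Cytokine and NF-kB target genes rose in 15 of 20 and fell in none (16 and 1 over the list alone, camera adjusted p = 1.88e-18), with a median of 1.74, or 1.27 with the member at 0 reads at its bound. The macrophage marker *Cd14* also rose, 2.07-fold, and the summed level of the macrophage markers was 17.1 ± 1.70 CPM with PDGF and 9.64 ± 2.39 CPM without. The cytokine list included *Hbegf*, an EGF receptor ligand (20.5-fold), and *Il6*, which had 99 reads against 2 (ratio 62.0, 95% counting interval 16.7 to 519). *Cish*, a feedback inhibitor of cytokine signalling, had 110 reads against 0 and was at least 45.9-fold higher. *Fgl2* had 102 reads against 2 (ratio 63.9, interval 17.2 to 534) and the hormone gene *Stc1* 145 against 2 (ratio 90.8, interval 24.7 to 757).

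Genes of ATF4 and the amino acid response rose in 23 of 33 and fell in none (24 and 1 over the list alone, median 0.85, camera adjusted p = 3.95e-12). The amino acid transporter genes *Slc7a1* and *Slc7a5* rose 3.39-fold and 2.50-fold. Ribosome biogenesis factors rose in 23 of 29 and fell in none (24 and 0 over the list alone, median 0.70, camera adjusted p = 5.72e-07, and adjusted p = 0.0516 with an estimated correlation). The nucleolar helicase gene *Ddx21* rose 2.34-fold. Cholesterol synthesis genes rose in 11 of 18 and fell in 1 (12 and 1 over the list alone, camera adjusted p = 8.99e-06). *Insig1*, a brake on the processing of the sterol regulator SREBP, rose 2.31-fold. NRF2 targets rose in 4 of 9 and fell in 1 (4 and 1 over the list alone, camera adjusted p = 0.000545, and adjusted p = 0.0556 with an estimated correlation). *Srxn1*, an antioxidant enzyme, rose 5.96-fold, and the list's median of 0.17 turned to −0.08 under library-size scaling. Cytosolic ribosomal protein genes did not pass (22 of 54 higher, none lower; 23 and 0 over the list alone, camera adjusted p = 0.119).

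Mitosis genes fell in 7 of 15 and rose in none (0 and 8 over the list alone, median −0.34, camera adjusted p = 0.0203, and adjusted p = 0.489 with an estimated correlation). *Cenpf*, a kinetochore protein, was 1.94-fold lower and the proliferation marker *Mki67* 1.23-fold lower. Extracellular matrix genes moved both ways, 7 of 22 higher and 7 lower (8 and 7 over the list alone). Their median was −0.05, or −0.01 with the member at 0 reads at its bound, while their mean was 0.57 and camera called them up (adjusted p = 0.0469). *Thbs1*, the hyaluronan synthase gene *Has2* (9.15-fold) and tenascin C, *Tnc* (21.8-fold), were among those that rose. The camera call was lost with an estimated correlation (adjusted p = 0.364), without replicate 2 or 3 of the group without PDGF (adjusted p up to 0.0720), under library-size scaling, without a filter, with transcripts as deposited and on the compared groups alone. FOXO and quiescence genes did not pass (5 of 18 higher, 10 lower; 5 and 11 over the list alone, camera adjusted p = 0.387), although *Fbxo32*, a ubiquitin ligase, fell 6.07-fold.

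In all, 2128 genes were higher and 1794 lower with PDGF, 37.0% of the 10603 tested, and 1625 of them changed at least 2-fold. Of the changed genes, 3690 had no overlap between the replicates of the groups, a state that held for 46.2% of all genes tested and that chance gives for 10%. The call on the same libraries favours such genes, so the 3690 are not separate support. Library-size scaling lowered the median change of all genes to −0.26 and the share of changed genes that were higher from 54.3% to 30.7% (1379 higher, 3111 lower).

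**Figure D2:**
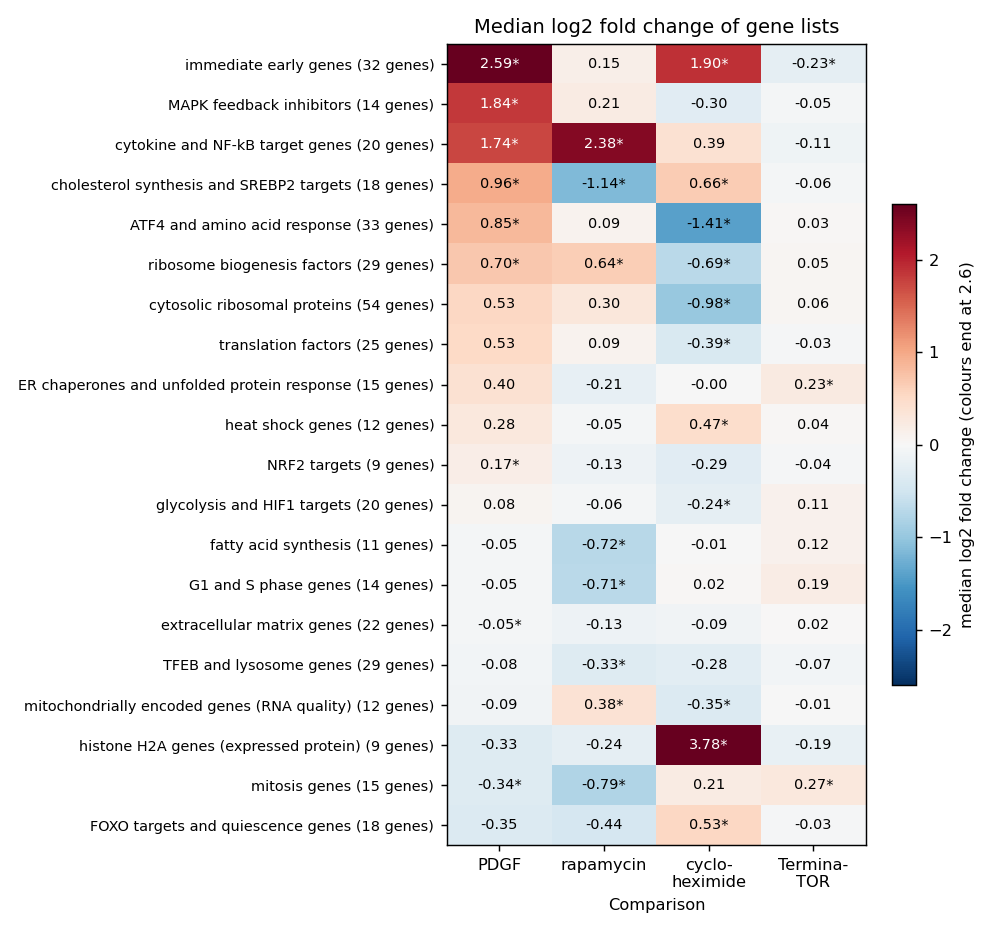
Heatmap of the median log2 fold change of the 20 gene lists that camera called in at least 1 of the 4 main comparisons, with lists as rows and comparisons as columns; an asterisk marks an adjusted p under 0.05, and the colour scale ends at 2.6. Immediate early genes had a median of 2.59 with PDGF, 1.90 with cycloheximide and −0.23 with TerminaTOR, and the median of NRF2 targets with PDGF (0.17) changed sign under library-size scaling (−0.08). In TerminaTOR cells 8 of 32 immediate early genes were called lower and 2 higher, and camera's call was lost with an estimated correlation (adjusted p = 0.196).

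The rapamycin comparison asked what inhibition of mTORC1 in the whole cell does to PDGF-treated control cells. Rapamycin raised cytokine and NF-kB target genes. *Csf3* (ENSMUSG00000038067.2, chromosome 11, 98701263 to 98703629), the granulocyte growth factor G-CSF, rose 348-fold (log2 8.44 ± 0.24 SE, 236 ± 8.70 against 0.683 ± 0.606 CPM, SD, n = 3), complement *C3* 21.6-fold and the cytokine gene *Lif* 19.5-fold. The level of *Csf3* with PDGF alone rested on few reads, with an SD close to its mean. Its fold is therefore imprecise, and its SE may understate the error. The pentraxin gene *Ptx3*, on chromosome 3 (66219910 to 66225805), rose by a log2 change of 4.53 ± 0.08 (1828 ± 95.2 against 79.4 ± 3.61 CPM), and the interferon-inducible GTPase gene *Gbp2* by 4.64 ± 0.09 (786 ± 106 against 31.4 ± 1.83 CPM). *Insig1* (ENSMUSG00000045294.11, chromosome 5, 28071363 to 28078662) fell 4.64-fold, from 528 ± 38.5 to 114 ± 18.6 CPM, and the stearoyl-CoA desaturase gene *Scd2* 4.13-fold, from 4104 ± 194 to 994 ± 24.8 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.11e-42 for *Csf3*, 1.29e-54 for *Ptx3* and 1.89e-31 for *Insig1*.

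Cytokine and NF-kB target genes rose in 18 of 20 and fell in none (18 and 0 adjusted over the list alone), with a median log2 change of 2.38 (camera adjusted p = 6.73e-52). The adhesion molecule *Vcam1* rose 7.61-fold from 232 ± 6.85 to 1763 ± 198 CPM and the chemokine *Ccl7* 6.57-fold. Of the macrophage markers, *Cd14* and *Lyz2* could be tested and neither was called higher: *Cd14* was at a log2 change of 0.33 ± 0.25 (edgeR adjusted p = 0.341) and *Lyz2* fell by 2.04 on the log2 scale. Ribosome biogenesis factors rose in 21 of 29 and fell in none (23 and 0 over the list alone, median 0.64, camera adjusted p = 7.71e-12). *Noc3l* rose 2.30-fold and *Rrp12* 2.27-fold. Mitochondrially encoded genes, a sign of RNA quality, were higher in 8 of 12 and lower in none (8 and 0 over the list alone, median 0.38, camera adjusted p = 0.0192, and adjusted p = 0.383 with an estimated correlation), a call also lost under library-size scaling. Mitochondrial genes took at least 9.84% of all counts in the libraries with rapamycin and 8.69% to 9.29% with PDGF alone.

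Cholesterol synthesis genes fell in 14 of 18 and rose in none (0 and 14 over the list alone, median −1.14, camera adjusted p = 5.23e-21). Fatty acid synthesis genes fell in 6 of 11 and rose in 1 (1 and 6 over the list alone, camera adjusted p = 2.06e-07), among them the elongase gene *Elovl6* (2.43-fold lower). Mitosis genes fell in 11 of 15 and rose in none (0 and 12 over the list alone, median −0.79, camera adjusted p = 1.07e-08, and adjusted p = 0.0542 with an estimated correlation). The checkpoint kinase gene *Bub1b* was 3.75-fold and *Mki67* 1.97-fold lower. G1 and S phase genes fell in 9 of 14 and rose in 1 (1 and 9 over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.0542 with an estimated correlation). *Mcm2*, a subunit of the replicative helicase, was 1.86-fold lower, and the list's call was also lost with transcripts as deposited. TFEB and lysosome genes fell in 13 of 29 and rose in 2 (2 and 13 over the list alone, median −0.33, camera adjusted p = 0.00409, and adjusted p = 0.184 with an estimated correlation). The proton pump subunit gene *Atp6v1b2* was 1.88-fold lower.

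Immediate early genes moved both ways with rapamycin, 12 of 32 higher and 8 lower (14 and 10 over the list alone, camera adjusted p = 0.458). *Fos* fell 1.44-fold and *Klf4* 1.81-fold, *Tiparp* rose 2.09-fold, and *Myc* and *Egr1* were not called (edgeR adjusted p = 0.470 and 0.738). The call for *Fos* (edgeR adjusted p = 0.000438) was lost with limma-voom (adjusted p = 0.185, the highest over its alternatives). Among the largest falls, *Edn1*, which encodes endothelin 1, had 3 reads against 60 (ratio 0.0558, interval 0.0112 to 0.171), and *Pcolce*, an enhancer of procollagen processing, was 8.03-fold lower.

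Rapamycin changed 3430 genes, 1724 higher and 1706 lower, 1169 of them at least 2-fold. Library-size scaling lowered the median change of all genes to −0.10 and the share of changed genes that were higher from 50.3% to 35.7%. Among the 2128 genes that PDGF raised, 756 rose further with rapamycin and 323 fell (789 and 349 adjusted over the list alone), and among the 1794 that PDGF lowered, 198 rose and 579 fell (212 and 604). Independent lists would share 346, 342, 292 and 289. The direction of the rapamycin change was tied to that of the PDGF change (odds ratio 6.84, Fisher's exact test, p = 8.67e-83). That test counts genes as independent, so its p overstates the evidence. Camera called the PDGF-induced genes up and the PDGF-repressed genes down (adjusted p = 5.51e-07 and 2.42e-06). With an estimated correlation, camera gave adjusted p = 0.00058 and 0.000178. These sets were chosen on the same PDGF libraries and are not independent evidence. Across genes, which are not independent replicates, the PDGF and rapamycin changes had a Pearson correlation of 0.130 and a covariance of 0.105, against −0.186 and −0.0812 for simulated unchanged groups, which share the PDGF libraries; the difference of the covariances was 0.186. Under library-size scaling the PDGF-induced genes that rose numbered 461 and the PDGF-repressed genes that fell 1186, and without a filter 105 PDGF-repressed genes rose. Against no PDGF, cells with rapamycin and PDGF had 2948 genes higher and 2708 lower (1918 and 4153 under library-size scaling, 52.1% and 31.6% of the changed genes higher). These included 1739 (81.7%) of the PDGF-induced and 1440 (80.3%) of the PDGF-repressed genes in the same direction, part of which may come from the shared libraries without PDGF.

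**Figure D3:**
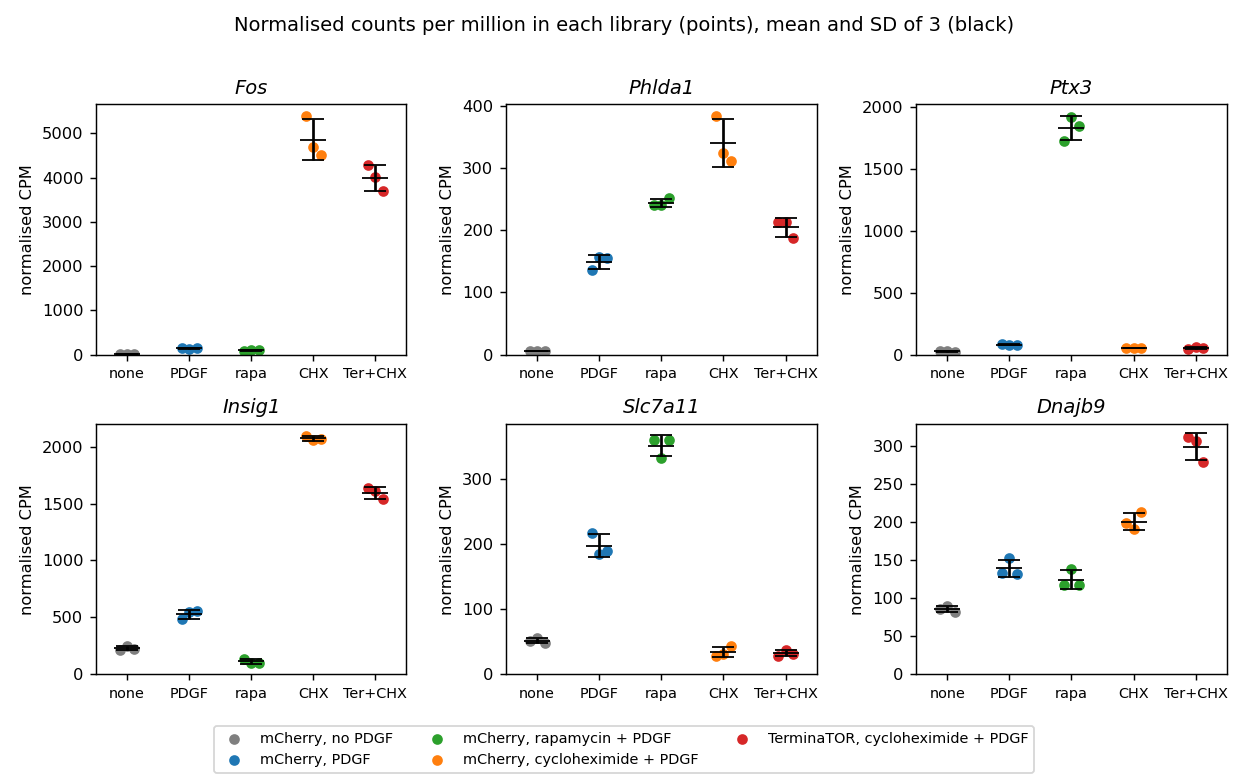
Normalized CPM per library for *Fos*, *Phlda1*, *Ptx3*, *Insig1*, *Slc7a11* and *Dnajb9* in the 5 groups; points are libraries, and bars mark the mean ± SD (n = 3). *Ptx3* stands highest with rapamycin (1828 ± 95.2 CPM), and *Fos* (4859 ± 463 CPM) and *Insig1* (2074 ± 20.6 CPM) in control cells with cycloheximide.

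The cycloheximide comparison asked what a block of translation does to PDGF-treated control cells, the background on which TerminaTOR was tested. Cycloheximide raised immediate early and histone genes. *Fos* rose 34.9-fold (log2 5.13 ± 0.10 SE; 4859 ± 463 against 139 ± 6.24 CPM, SD, n = 3) and the transcription factor *Klf6* (ENSMUSG00000000078.7, chromosome 13, 5861482 to 5870394) 4.93-fold (7724 ± 436 against 1567 ± 36.1 CPM). *Hist1h4i*, a gene of histone H4 (chromosome 13, 22040636 to 22041362), rose 39.9-fold from 5.97 ± 1.54 to 240 ± 22.5 CPM. The threonyl-tRNA synthetase gene *Tars* fell 65.0-fold, *Dlk1*, an inhibitor of adipocyte formation, 35.9-fold, and *Slc7a11*, the cystine transporter, 5.74-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.18e-19 for *Fos*, 1.45e-35 for *Hist1h4i* and 1.76e-21 for *Tars*.

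Immediate early genes rose in 26 of 32 and fell in 3 (26 and 3 adjusted over the list alone, median log2 change 1.90, camera adjusted p = 4.26e-54). The AP-1 subunit *Jund* rose 7.82-fold and *Egr1* 7.05-fold, while *Myc* was not called (log2 −0.65; edgeR adjusted p = 0.188). Histone H2A genes rose in 6 of 9 and fell in 2 (7 and 2 over the list alone, median 3.78, or 3.19 with members at 0 reads at their bound; camera adjusted p = 1.42e-05), with *H2afx*, the variant that marks DNA breaks, up 5.28-fold. Reads of these near-identical genes may be split between copies. *Hist1h1a* had 288 reads against 1 (ratio 253, interval 45.1 to 10046). *Fcgr1* rose 36.8-fold, but it lies beside histone genes on chromosome 3 (96282909 to 96293969), so its reads may come from neighbours.

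Cholesterol synthesis genes rose in 13 of 18 and fell in 1 (13 and 1 over the list alone, median 0.66, camera adjusted p = 8.90e-09). *Insig1* rose 3.93-fold. FOXO and quiescence genes rose in 10 of 18 and fell in 2 (10 and 3 over the list alone, camera adjusted p = 5.70e-06). *Foxo3* itself rose 6.24-fold and the antiproliferative gene *Tob1* 4.89-fold. Heat shock genes rose in 6 of 12 and fell in 2 (6 and 3 over the list alone, camera adjusted p = 7.96e-05, and adjusted p = 0.0518 with an estimated correlation). The chaperone genes *Hspa1b* and *Dnajb1* rose 4.18-fold and 12.8-fold.

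ATF4 and amino acid response genes fell in 29 of 33 and rose in 1 (1 and 29 over the list alone, median −1.41, camera adjusted p = 1.57e-22). *Slc7a1* was 4.19-fold and *Slc7a5* 2.94-fold lower. Ribosome biogenesis factors fell in 24 of 29 and rose in 1 (1 and 24 over the list alone, median −0.69, camera adjusted p = 7.17e-09), and *Rrs1* was 2.88-fold lower. Cytosolic ribosomal protein genes fell in 38 of 54 and rose in none (0 and 40 over the list alone, median −0.98, camera adjusted p = 7.32e-07), from *Rpl10a* (5.12-fold lower) to *Rps3a1* (1.31-fold lower, 5499 ± 214 against 7228 ± 290 CPM). Translation factors fell in 14 of 25 and rose in none (0 and 15 over the list alone, camera adjusted p = 0.00179), for example *Eif4a2*, an RNA helicase of initiation (2.33-fold lower). Glycolysis and HIF1 targets fell in 9 of 20 and rose in 3 (3 and 9 over the list alone, camera adjusted p = 0.0347, and adjusted p = 0.0963 with an estimated correlation), and the hexokinase gene *Hk2* was 2.03-fold lower. The list's call was also lost without replicate 1 of the cycloheximide control group (adjusted p = 0.0691) and on the compared groups alone. Mitochondrially encoded genes fell in 7 of 12 and rose in none (0 and 7 over the list alone, camera adjusted p = 0.0347, and adjusted p = 0.401 with an estimated correlation), a call also lost without replicate 2 of the PDGF group (adjusted p = 0.0527), and took 6.27% to 6.64% of all counts.

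Cycloheximide changed 4310 genes, 2231 higher and 2079 lower, 1971 of them at least 2-fold. Library-size scaling lowered the median change of all genes to −0.13 and the share of changed genes that were higher from 51.8% to 39.0%. Against no PDGF, 2611 genes were higher and 2417 lower with cycloheximide and PDGF (1615 and 4400 under library-size scaling, where the median of all genes was −0.40). Of the PDGF-induced genes 1339 (62.9%) were higher and of the PDGF-repressed genes 1049 (58.5%) lower, part of which may come from the shared libraries without PDGF. No library had cycloheximide without PDGF, so this response mixes both treatments.

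The TerminaTOR comparison asked which transcripts depend on mTORC1 in the nucleus, with translation blocked. The median absolute log2 change among changed genes was 0.39, against 0.84 with PDGF, 0.76 with rapamycin and 0.92 with cycloheximide. *Phlda1* fell 1.66-fold (log2 −0.73 ± 0.07 SE; 205 ± 14.7 against 340 ± 38.5 CPM, SD, n = 3), *Klf6* 1.45-fold (5319 ± 419 against 7724 ± 436 CPM) and *Tiparp*, an ADP-ribosyltransferase gene, 1.53-fold. *Dnajb9* (chromosome 12, 44205559 to 44210326), a chaperone of the endoplasmic reticulum, rose 1.49-fold (299 ± 17.9 against 201 ± 11.1 CPM), the collagen gene *Col5a2* 1.39-fold, and *Egr4* (chromosome 6, 85511121 to 85513589), an immediate early transcription factor, 2.91-fold (48.9 ± 9.44 against 17.0 ± 3.06 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 2.22e-11 for *Phlda1*, 1.21e-09 for *Klf6*, 5.48e-08 for *Dnajb9* and 1.25e-07 for *Egr4*. The fusion proteins are carried by separate stable lines, so an effect of TerminaTOR and a difference between the lines cannot be told apart in any of these values.

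Immediate early genes fell in 8 of 32 and rose in 2 (2 and 11 adjusted over the list alone, median log2 change −0.23, camera adjusted p = 3.49e-09, and adjusted p = 0.196 with an estimated correlation). *Fos* was at 3997 ± 295 against 4859 ± 463 CPM and was not called (log2 −0.28 ± 0.08; edgeR adjusted p = 0.0561), and neither were *Myc* (0.256) and *Egr1* (0.334). Mitosis genes rose in 5 of 15 and fell in none (8 and 0 over the list alone, median 0.27, camera adjusted p = 4.22e-06, and adjusted p = 0.196 with an estimated correlation). Among them the call of the topoisomerase gene *Top2a* (1.26-fold; edgeR adjusted p = 0.00364) was lost without replicate 1 of the cycloheximide control group (adjusted p = 0.127, the highest with a replicate left out). ER chaperones rose in 3 of 15 and fell in none (4 and 0 over the list alone, median 0.23, camera adjusted p = 0.000955, and adjusted p = 0.196 with an estimated correlation), *Dnajb9* among them.

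Of the lists called with rapamycin, mitosis genes were called here too, in the opposite direction, lower with rapamycin and higher with TerminaTOR, and both calls were lost with an estimated correlation (adjusted p = 0.0542 and 0.196). None of the other lists called with rapamycin passed here. Fatty acid synthesis, G1 and S phase and mitochondrially encoded genes had no member called, also over the list alone (camera adjusted p = 0.257, 0.0730 and 0.828). The median of the G1 and S phase genes was 0.19. The rest were cytokine and NF-kB targets (2 of 20 higher, 2 lower; 2 and 2 over the list alone, camera adjusted p = 0.725), cholesterol synthesis (1 of 18 higher, 3 lower; 1 and 3; 0.402), ribosome biogenesis factors (4 of 29 higher, none lower; 5 and 0; 0.160) and TFEB and lysosome genes (2 of 29 higher, 7 lower; 3 and 8; 0.203). Within them, *Insig1* fell 1.30-fold (1594 ± 51.9 against 2074 ± 20.6 CPM), the heparin-binding growth factor gene *Hbegf* rose 1.36-fold, nucleolin, *Ncl*, rose 1.26-fold, and *Ulk1*, a kinase that starts autophagy, rose 1.36-fold. *Ifit1* and *Isg15*, interferon-induced genes, rose 1.52-fold and 1.72-fold, in a list that did not pass (2 of 9 higher, 1 lower; 2 and 1; 0.118). Of the 16 largest changes, 6 kept their call with each replicate left out in turn: *Olr1*, a scavenger receptor (49 against 6 reads, 7.36-fold higher), *Egr4*, the DNA repair exonuclease gene *Exo1* (2.46-fold higher), the growth-cone protein gene *Gap43* (5.70-fold lower), *Naxd*, an enzyme of NADH repair (5.54-fold lower), and the Fanconi anemia gene *Fancc* (3.44-fold lower). The call of *Naxd* was lost with transcripts as deposited.

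TerminaTOR cells had 249 genes higher and 273 lower, 4.92% of those tested, and 50 of them changed at least 2-fold. Of the 522, 513 had no overlap between replicates, against 23.7% of all genes tested and 10% by chance. The call on the same libraries favours such genes, so the 513 are not separate support. Library-size scaling gave 321 higher and 210 lower, 60.5% higher against 47.7%. Leaving out a replicate gave 340 and 320 changed genes without replicates 1 and 3 of the cycloheximide control group, and 308 and 319 without replicates 1 and 3 of the TerminaTOR group; a fit on these 6 libraries alone gave 804. PDGF-induced genes showed no common direction, with 106 of 2128 higher and 124 lower (camera adjusted p = 0.882), nor did PDGF-repressed genes, with 64 of 1794 higher and 64 lower (camera adjusted p = 0.960). Adjusted over the list alone, the counts were 137 and 162, and 76 and 73, and the odds ratio of the directions was 0.855 (Fisher's exact test, p = 0.509). Under library-size scaling 79 PDGF-induced genes were lower and 128 PDGF-repressed genes higher, and without a filter 30 PDGF-repressed genes were lower.

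The last comparison asked whether genes moved by rapamycin in the whole cell are also moved by TerminaTOR in the nucleus. In both, *Adamts1*, a matrix protease gene, fell (log2 −0.59 ± 0.07 SE with TerminaTOR and −0.66 ± 0.07 with rapamycin, n = 3 each), as did *Klf4* (−0.41 and −0.86), *Klf13* (−0.46 and −0.73), the matrix metalloproteinase gene *Mmp14* (−0.44 and −0.59) and *Hist1h1c* (−0.42 and −2.91). *Cd55*, a complement regulator (0.70 and 0.63), *Hbegf* (0.45 and 0.88), *Svep1* (0.51 and 0.64) and the prostaglandin synthase gene *Ptges* (0.52 and 0.83) rose in both. *Phlda1* fell with TerminaTOR and rose with rapamycin (−0.73 and 0.71), and *Vdr*, the vitamin D receptor gene, rose and fell (0.72 and −0.65). All these calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

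The 327 genes changed in both settings comprised 60 higher in both, 88 lower in both, 95 lower with rapamycin and higher with TerminaTOR, and 84 the reverse. Independent lists would share 40.5, 43.9, 40.1 and 44.4, and each overlap was larger (Fisher's exact test, adjusted over a family of 28, p = 0.00138, 3.87e-11, 3.43e-17 and 2.43e-09). With an excess in every pair of directions, these tests cannot tell shared targets from genes that are called more readily in any comparison. Opposite directions held for 179 and matching directions for 148 genes, or 97 without a filter. Across all genes, which are not independent replicates, the changes had a Pearson correlation of −0.0142 and a Spearman correlation of −0.0181. The overlap was 217 and 198 without replicates 1 and 3 of the cycloheximide control group, and 200, 214 and 202 without replicates 1, 2 and 3 of the TerminaTOR group. The effects themselves differed for 2548 genes, 1320 higher and 1228 lower with TerminaTOR than with rapamycin (1855 and 867 under library-size scaling, with a median of 0.14). Rapamycin was given without cycloheximide and TerminaTOR with it, so this difference also holds the difference in setting. An excess over independent lists in every pair of directions was not special to rapamycin, since PDGF and TerminaTOR calls showed it too. Of the PDGF-induced genes, 106 were higher and 124 lower with TerminaTOR, against 49.97 and 54.79 for independent lists. Of the PDGF-repressed genes, 64 were higher and 64 lower, against 42.13 and 46.19.

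**Figure D4:**
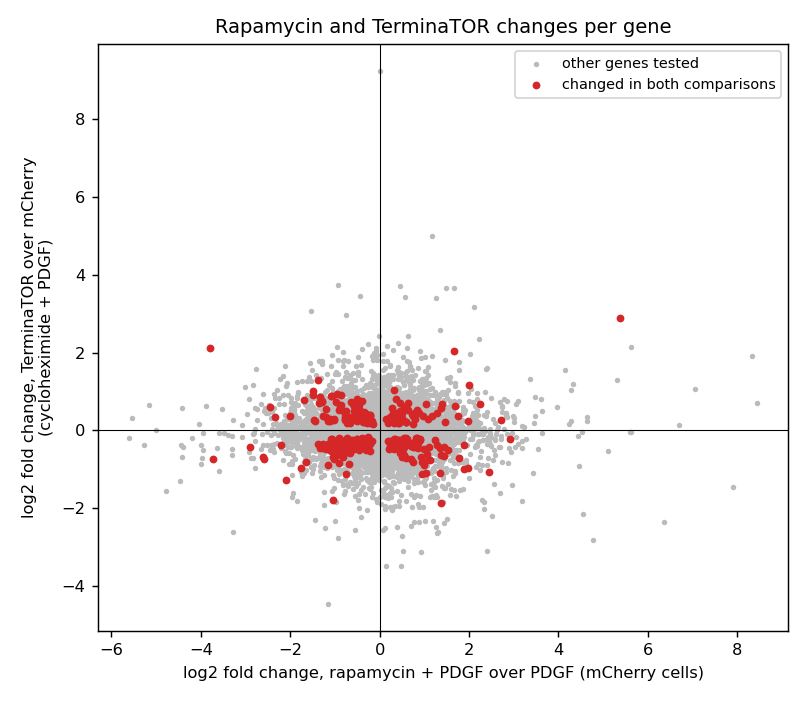
Log2 fold change with rapamycin (x axis) against that with TerminaTOR (y axis) for each of the 10603 genes tested, with the 327 genes changed in both in red. The red points fall in all 4 quadrants, 148 with matching and 179 with opposite signs.

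The remaining lists passed camera in none of the 4 main comparisons, and their members are given as higher and lower for PDGF, rapamycin, cycloheximide and TerminaTOR in turn. Of 18 genes of mTORC1 components, 4 and 3, 3 and 4, 5 and 5, and 2 and 0 were called (4 and 3, 3 and 4, 6 and 5, and 2 and 0 over the list alone). *Mtor* itself was 1.58-fold higher with cycloheximide. SRF and MRTF cytoskeletal targets (13 tested) gave 3 and 3, 3 and 4, 7 and 2, and 2 and 0 (4 and 3, 3 and 4, 7 and 2, and 2 and 0 over the list alone), with *Tpm1*, a tropomyosin gene, up by a log2 change of 2.04 ± 0.15 and *Acta2*, an actin gene, 2.16-fold lower with rapamycin. Interferon response genes (9 tested) gave 2 and 1, 4 and 3, 3 and 1, and 2 and 1 (2 and 1, 5 and 3, 3 and 1, and 2 and 1 over the list alone), with *Ifit1* 5.50-fold lower with rapamycin and 4.71-fold higher with cycloheximide. Oxidative phosphorylation genes (16 tested) gave 3 and 0, 2 and 2, 0 and 3, and 2 and 1, the same over the list alone, with *Ppargc1a*, a regulator of mitochondrial genes, down by a log2 change of −2.59 ± 0.26 with rapamycin. The p53 targets (12 tested) gave 2 and 3, 3 and 1, 1 and 3, and 0 and 0, the same over the list alone. Nucleotide synthesis genes (9 tested) gave 2 and 2, 3 and 2, 1 and 2, and 0 and 1 (4 and 2 with rapamycin over the list alone), and snoRNA host genes (10 tested) 4 and 1, 3 and 0, 2 and 4, and 0 and 0, the same over the list alone.

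Of the smaller lists, RNA polymerase III genes (10 tested) gave 2 and 3, 1 and 3, 2 and 1, and 0 and 0, the pentose phosphate pathway (5 tested) 1 and 2, 0 and 1, 2 and 2, and 0 and 0, and nuclear retained RNAs (8 tested) 6 and 1, 2 and 0, 1 and 0, and 0 and 1, each the same over the list alone. PDGF receptors and ligands (4 tested) gave 0 and 1, 2 and 0, 0 and 1, and 0 and 0, also the same over the list alone, with the receptor gene *Pdgfra* 2.74-fold higher with rapamycin (a call lost with transcripts as deposited) and 3.33-fold lower with cycloheximide. Few markers of other cell types passed the filter. Macrophage markers (2 tested) gave 1 and 0, 0 and 1, 0 and 0, and 0 and 0, endothelial markers (3 tested) 1 and 0, 0 and 0, 0 and 1, and 0 and 0, the same over the list alone. Of the adipocyte markers *Lpl*, a lipoprotein lipase, was tested and fell 5.17-fold with rapamycin, and over the list alone it was also called higher with TerminaTOR. The 1 epithelial marker tested was called over the list alone, lower with TerminaTOR, and no muscle marker passed the filter.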

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

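All alternatives below were chosen before the data were examined. With each replicate left out in turn, 3388 to 3673 genes changed with PDGF (3922 with all), 2864 to 3192 with rapamycin (3430), 3754 to 3928 with cycloheximide (4310) and 308 to 367 in TerminaTOR cells (522). Against no PDGF the ranges were 4564 to 4775 with cycloheximide (5028) and 5339 to 5550 with rapamycin (5656), and 2237 to 2480 genes differed between the TerminaTOR and rapamycin effects (2548). The overlap of rapamycin and TerminaTOR calls ran from 198 to 343 (327), in the same direction from 91 to 161 (148) and in opposite directions from 106 to 182 (179). Of the PDGF-induced genes, 65 to 107 were higher (106) and 75 to 124 lower (124) with TerminaTOR, and of the PDGF-repressed genes 35 to 67 were higher (64) and 33 to 68 lower (64). The lowest counts that involve TerminaTOR calls came from leaving out replicate 3 of the cycloheximide control group or replicate 1 or 3 of the TerminaTOR group. A group then holds fewer libraries, and the cause beyond that was not tested. The number of lists called was 8 to 9 with PDGF (9) and with rapamycin (8), 10 to 12 with cycloheximide (11) and 3 to 4 with TerminaTOR (3).

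Among named genes, leaving out a replicate ended at least 1 call for 10 of 107 with PDGF, 6 of 106 with rapamycin, 6 of 106 with cycloheximide and 32 of 71 with TerminaTOR. Of the 16 largest changes per comparison it ended none in the first 3 of these comparisons and 10 with TerminaTOR. The cause was not tested.

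Library-size scaling gave 461 PDGF-induced genes higher (756) and 1186 PDGF-repressed genes lower with rapamycin (579), and 79 PDGF-induced genes lower (124) and 128 PDGF-repressed genes higher with TerminaTOR (64). It moves the median of all genes, to −0.26 with PDGF, −0.10 with rapamycin and −0.13 with cycloheximide. Under it *Yy1* turned from a log2 change of 0.22 to −0.028 with PDGF (adjusted p = 0.708). Without a filter, 97 genes overlapped in the same direction (148), 105 PDGF-repressed genes were higher with rapamycin (198) and 30 lower with TerminaTOR (64); the cause was not tested. A fit on the compared groups only called 804 genes with TerminaTOR (522), with the spread taken from those 6 libraries.

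A 2-fold minimum left 1625 genes with PDGF, 1169 with rapamycin, 1971 with cycloheximide and 50 with TerminaTOR, and 2598 and 3238 for cycloheximide and rapamycin against no PDGF. An adjusted p under 0.01 left 269 genes with TerminaTOR. With an estimated correlation camera called 5 lists with PDGF (9), 4 with rapamycin (8) and 0 with TerminaTOR (3), and fry, which does not compare a list with other genes, called 27, 22, 18 with cycloheximide (11) and 6. The unadjusted p with an estimated correlation in TerminaTOR cells was 0.0178 for immediate early genes, 0.0237 for mitosis genes and 0.00911 for ER chaperones.

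The replicate numbers showed no strong pairing of the libraries at a cut-off of 0.1, and a weak pairing is not excluded. Deviations of same-numbered libraries correlated above 0.1 for every number in 0 of 10 pairs of groups, and 8 of 15 libraries correlated best with their own number. With the replicate number as a block, 3933 genes changed with PDGF, 3444 with rapamycin, 4332 with cycloheximide, 563 with TerminaTOR, 5041 and 5653 against no PDGF, and 2587 for the difference. The block ended no call of a list and, among named genes, those of *Hist1h2ad* with rapamycin and *Itga1* with TerminaTOR.

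The other counts of changed genes, with median-of-ratios scaling, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom and transcripts as deposited, stayed within 1.5 times the values in brackets. Depth limits genes with few reads: at 3466202 to 6777780 reads per library, a group without a read allows up to 3 counts over its 3 libraries.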

Other observations

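The tests of leukocytes, of library scaling, of RNA without a poly(A) tail, of reads shared between histone genes and of a weaker cycloheximide effect were chosen after the results they bear on were seen, and those of isoform use before.

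Replication-dependent histone genes, whose messages lack a poly(A) tail and accumulate in S phase, were examined beyond the histone H2A list. This set was chosen after the values were seen, and no set test was run on it. Of 39 tested, 38 were higher with cycloheximide (median log2 change 4.19, or 3.85 with members at 0 reads at their bound), and their summed level rose from 224 ± 18.2 to 2359 ± 105 CPM (SD, n = 3). With rapamycin 11 were lower and 0 higher (median −1.18, or −0.98 at the bound), with a sum of 69.3 ± 5.74 CPM, by edgeR's quasi-likelihood test. The share of reads on rRNA genes was lower there too, 0.635% to 1.61% against 2.25% to 3.33% with PDGF alone, while the 21 small non-coding and rRNA genes tested had a median log2 change of 0.18 with 2 higher and 2 lower, so less RNA without a poly(A) tail in the rapamycin libraries stays open. With PDGF 7 were higher and 1 lower, from a sum of 144 ± 3.27 CPM. In TerminaTOR cells 8 were lower and 0 higher (median −0.46), with a sum of 1748 ± 155 CPM.

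The cytokine and NF-kB target genes were higher with rapamycin, and their summed level was 2616 ± 158 CPM without PDGF, 19280 ± 480.1 with PDGF and 58990 ± 1967 with rapamycin and PDGF. Leukocytes brought in with rapamycin would raise the macrophage markers too, but their sum, over the 6 of 10 markers with reads, was 17.8 ± 0.923 against 17.1 ± 1.70 CPM, a ratio of 1.04. Library scaling left the list's median at 2.25 or more. Of the 29 called transcripts of these genes, of 33 tested, 100% were higher, so no shift between transcripts that both have counted reads was seen. Reads shared by transcripts are not counted, so a shift from an isoform without reads of its own could give rises alone. A change of isoform use thus stays open. Neither leukocytes, as far as these markers show, nor library scaling accounted for the pattern. The cells are an established fibroblast line, and the scalings differed little, with a median of all genes from 0.02 to −0.10. Neither test was thus likely to come out otherwise, and they add little to what follows. A response to rapamycin is a hypothesis that remains, found and tested on the same libraries.

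The replication-dependent histone genes were higher with cycloheximide. More RNA without a poly(A) tail in those libraries would raise the 21 small non-coding and rRNA genes tested as well, but their median log2 change was −0.34 (quartiles −1.13 to 0.76), with 1 higher and 3 lower. Reads split between near-identical histone genes would shift counts among copies and leave the family sum, which was 10.6 times higher. If shared reads were instead dropped in counting, the sum would not hold them. The sum cannot decide on a change in how many reads were dropped. A longer poly(A) tail on histone messages themselves was not tested. A change in the level of histone messages under a block of translation is a hypothesis that remains.

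Of 32 immediate early genes, 8 were called lower and 2 higher in TerminaTOR cells, and camera's call of the list as lower was lost with an estimated correlation (adjusted p = 0.196). Library scaling left their median at −0.20 or below. A weaker cycloheximide effect, as a whole or on the most strongly raised genes, cannot be told apart. Of the genes that cycloheximide raised, 104 of 208 called in both were lower (50%, exact 95% interval 43.0% to 57.0%), but weakly raised genes would move little. In tests chosen after that one, among genes outside the list that cycloheximide raised at least 4-fold, 23 of 29 called were lower (79.3%, interval 60.3% to 92.0%), and 15 of 21 without the histone genes (71.4%, interval 47.8% to 88.7%). Of those it lowered at least 4-fold, 8 of 9 called were higher (11.1% lower, interval 0.281% to 48.3%). Both comparisons share the cycloheximide control libraries, which by itself favours opposite directions: 44.3% of genes had the same direction in simulated unchanged groups and 46.4% in the data, with covariances of −0.0864 and −0.0836. A change of isoform use cannot be told apart. The 8 called transcripts counted were those of genes already called lower. That 100% of them were lower was thus largely set beforehand, and 8 are too few. TerminaTOR itself and a difference between the stable lines stay open too, untested, because the design has no second line and no TerminaTOR library without cycloheximide.

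For each comparison of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05, and 1 of them, the real one, gave the largest count. The fit on those libraries called 3790 genes with PDGF, 3227 with rapamycin, 4317 with cycloheximide, 4663 with cycloheximide and PDGF against no PDGF and 5123 with rapamycin and PDGF against no PDGF, with 0 as the highest of the other splits in each, and 804 genes with TerminaTOR, with 1 as the highest. For the difference between the TerminaTOR and rapamycin effects, 1 of 100 splits drawn, the real one, gave 2661 genes and the highest of the others 2115. Splits that mixed the rapamycin and PDGF libraries gave 0 and reflect the rapamycin effect itself. Besides the real one, 7 kept those libraries apart and gave 1839 to 2115, too few for a share under 0.05.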
